A study of Mus musculus with 2 samples.

How the data were processed

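Mandibular prominences of wild-type CD1 mouse embryos were dissected at embryonic days 11.5 and 13.5, minced, and dissociated with a cold-active bacterial protease, per the labels' protocols. For each stage 12.5 mg of tissue was digested for 10 minutes with 3 mg/ml (E11.5) or 5 mg/ml (E13.5) of protease. About 9600 cells were loaded on a 10x Chromium instrument to capture 6000 cells. There was 1 library per stage. The number, litter and sex of the pooled embryos are not given in the sources used here.

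The authors deposited, for each library, a table of whole-number UMI counts per gene and cell and a metadata table. Cell Ranger 2.0.0, Seurat 2.3.4 and the mouse build mm10 are named, per the submitters' processing notes, which give no role or order for them. The gene annotation release, the read length, the cell filters and any removal of doublets are not given in the sources used here. In every cell the sum of the counts equalled 1 of the authors' 2 deposited count totals, and the other total held 2604 (E11.5) and 2631 (E13.5) further UMIs over all cells. The mitochondrial share is a fraction of 0 to 1 in the deposited metadata, despite a column name that calls it a percent, and is printed here as a percent. Cell cycle scores and phase calls, cluster numbers and lineage names are the authors' deposited values, and the gene lists behind the scores are not given in the sources used here. The score values themselves were not used, only the authors' phase calls. The tables list 16236 genes at E11.5 and 17775 at E13.5. Genes listed in both tables, 15944 in number, entered the comparisons, and 292 and 1831 genes listed in 1 table only did not. The deposited cells differ in their lowest UMI count (2253 and 500) and highest mitochondrial share (7.90% and 19.98%), so the 2 libraries were not filtered to the same limits. That changes shares of cells most for classes with shallow or stressed cells.

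The gene lists, cell type markers, comparisons and naming rule were fixed before the data were examined. Each deposited cluster was put in a broad class by the authors' lineage name, and checked against the fixed markers among its 10 leading genes. E11.5 cluster 17, named mesenchyme and neural crest by the authors, led with glial markers and was kept out of the mesenchyme (0.366% of the E11.5 cells). E11.5 cluster 14 had no lineage name and led with muscle markers. E13.5 cluster 20, named mast cells by the authors, led with macrophage markers. E13.5 cluster 8 had no lineage name and a median of 935.5 UMIs, and stayed unnamed. Values within a class were compared where both libraries held at least 50 of its cells, which left out macrophages and glia.

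For each class and library the UMI counts were summed over cells and divided by their sum to CPM. The ratio of E13.5 over E11.5 has an exact conditional binomial 95% interval, and a share of cells an exact Clopper-Pearson interval. With 1 library per stage there is no test, so no p-value is given. A list member was measured with at least 20 UMIs over both libraries, and called higher or lower when its ratio was at least 1.5-fold and its interval excluded 1. This is a rule of size, not a test. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Of 25 fixed lists with 393 genes, 24 were used, because the list of antigen presentation and macrophage maturation had no class with enough cells. Genes of 1 table only, such as Ibsp, were not measured members. The 2 members with the largest and the 2 with the smallest ratios stand as examples for the main lists, and Gli2, Gli3 and Hand2 are given throughout. Other genes were named by rank: the 12 highest and 12 lowest ratios in the mesenchyme, and 5 and 5 in each other class. They needed at least 100 CPM where higher, at least 50 UMIs, an interval wholly beyond 2-fold, and at least 0.2 of the gene's highest class level in that library as a guard against free RNA. Haemoglobin, mitochondrial, ribosomal protein, predicted and sex-linked marker genes were left out of that ranking. Values of a few genes are not reported. Any gene outside these rules is said to have been chosen after its values were seen.

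Shares of cells with a UMI of a gene were computed after drawing 2000 UMIs from each cell without replacement and leaving out shallower cells. Erythroid cells served as the background class. They are deep and rich in haemoglobin, so thinning can understate their free RNA. Coordinates are those of the GENCODE annotation of GRCm38 (mm10), matched by symbol. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5, and figures matplotlib 3.10.9. Doublets were kept in the main values. Scrublet, run in scanpy with an expected rate of 0.05, marked 8 of 7099 cells (0.113%) and 8 of 6318 cells (0.127%), too few to have worked, so the 5% of cells with the highest scores were left out in an alternative chosen after the data were seen.

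The ratios and list percentiles were tested on simulated data. On 13609 genes drawn at the depth of the mesenchyme, the interval lay on the right side of 1 for 100% of genes changed to 0.25 of their level, 91.1% of those changed to 0.5, 98.0% of those raised 2-fold and 100% of those raised 4-fold, and 95.3% of intervals held the true ratio. On 8638 genes at the depth of the endothelium these shares were 97.7%, 72.3%, 88.0% and 100%, and 96.0% of intervals held the true ratio. A simulated list of 15 mesenchyme genes raised 2-fold lay at percentile 100, and 15 unchanged genes at 69.8. Alternatives covered the scaling, the minimum UMI count, the weight and depth of cells, doublets, cell type calls, dividing cells, clusters in a class, free RNA, cell filters and embryo sex. Results of each list are given with its class in the report.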

Results

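The mandibular prominence is the part of the first pharyngeal arch that forms the lower jaw, the tongue and their covering. Single cells of this tissue from wild-type CD1 mouse embryos were profiled by droplet-based 10x RNA sequencing at embryonic day 11.5 (E11.5) and at embryonic day 13.5 (E13.5). At E11.5 the tissue held the tongue bud, and at E13.5 the growing tongue and skeletal elements. Each stage was 1 library, so 2 libraries were compared and there was no replicate check. The E11.5 library held 7099 cells and 49913485 UMIs (unique transcript counts), with a median of 6231 UMIs per cell, and the E13.5 library held 6318 cells and 67838169 UMIs, with a median of 9280. No p-value is given, because cells of 1 library are not replicates. All intervals are 95% intervals that cover counting error only. Stage could not be told apart from library or from the protease concentration used to dissociate the tissue (3 mg/ml at E11.5 and 5 mg/ml at E13.5). The libraries also differed in a marker of embryo sex: Xist, the transcript of the inactive X chromosome, was at 0.0536 CPM (UMIs scaled to a sum of 1e+06) in the E11.5 mesenchyme and at 499 CPM at E13.5. In cells with no Xist UMI, 0 of 50 list medians and 0 of 252 values of single genes were counted as turned in direction. A further 9 and 18 lay outside their intervals. This count can leave out sign changes of medians that did not stand out from the random lists, as given with the alternatives.

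The first comparison asked how the cell types of the prominence differed between the stages. Mesenchyme, the largely neural crest-derived tissue that gives rise to bone, cartilage, tendon and connective tissue, made up 83.1% of the E11.5 cells (82.2 to 84.0%) and 61.8% of the E13.5 cells (60.6 to 63.0%). Epithelium, the outer and oral covering, made up 5.71% (5.18 to 6.27%) at E11.5 and 13.3% (12.4 to 14.1%) at E13.5. Skeletal muscle, which the authors named tongue muscle at E13.5, made up 2.13% (1.80 to 2.49%) and 11.9% (11.1 to 12.7%). Endothelium, the lining of blood vessels, made up 2.28% (1.95 to 2.66%) and 2.17% (1.82 to 2.56%). Erythroid cells made up 6.42% (5.86 to 7.02%) at E11.5 and 3.28% (2.85 to 3.75%) at E13.5. Schwann cells and glia, from 26 and 102 cells, made up 0.366% (0.239 to 0.536%) and 1.61% (1.32 to 1.96%). A cluster led by macrophage genes held 73 cells, 1.16% (0.907 to 1.45%), at E13.5, and no E11.5 cluster led with these genes, although 22 cells of the E11.5 endothelial cluster held at least 3 UMIs of macrophage markers. A further E13.5 cluster of 304 cells (4.81%) stayed unnamed, with a median of 935.5 UMIs per cell. The deposited cells were not filtered alike: the lowest UMI count of a cell was 2253 at E11.5 and 500 at E13.5, and the highest mitochondrial share was 7.90% and 19.98%. With the E11.5 limits applied to both libraries, the E13.5 shares were 65.8% for mesenchyme, 12.4% for epithelium, 12.9% for skeletal muscle and 1.75% for endothelium, of which 100 of 137 cells were kept, so whether the endothelial share differed depends on the filters.

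**Figure D1:**
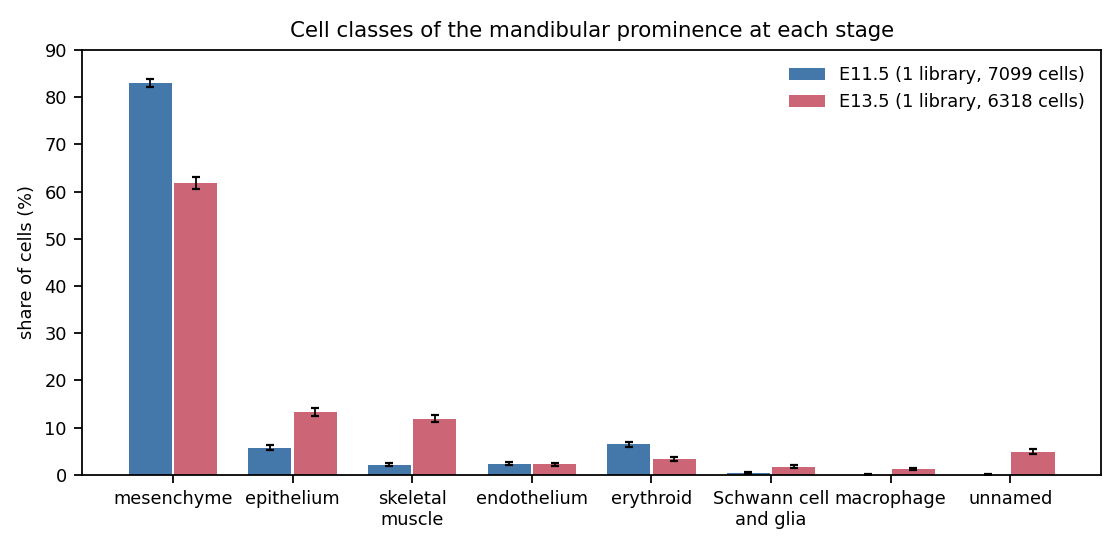
Bars give the share of cells (y axis, %) in each cell class (x axis) in the E11.5 library of 7099 cells and the E13.5 library of 6318 cells, and error bars give exact 95% binomial intervals for counting error. Mesenchyme lies at 83.1% and 61.8%, epithelium at 5.71% and 13.3%, and skeletal muscle at 2.13% and 11.9%.

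The second comparison asked which genes differed within the mesenchyme, where 14139 genes held at least 20 UMIs in both libraries together. Genes of skeletal and connective tissue were higher at E13.5. Of 19 measured genes of fibrillar and connective tissue matrix, 17 were at least 1.5-fold higher at E13.5 and 0 were lower, and the median log2 ratio of the list was 2.14. Col1a1, a chain of type I collagen, was at 181 and 660 CPM, 3.65-fold higher (3.56 to 3.75), and Col3a1, a chain of type III collagen, at 347 and 914 CPM, 2.63-fold higher (2.58 to 2.69), both chosen after their values were seen. Eln, which encodes elastin, was at 6.68 CPM at E11.5 and 112 CPM at E13.5, 16.8-fold higher (14.8 to 19.2). Col14a1 was 65.1-fold higher (27.6 to 202), yet its 8.72 CPM at E13.5 was under 0.2 of its level in another class and is within reach of free RNA. The smallest ratios were those of Mfap4 (447 and 535 CPM) and Fbln1 (202 and 257 CPM), 2 elastic fibre-associated proteins. Of 6 measured tendon genes, 5 were higher and 0 lower, with a median log2 ratio of 2.34. Over the 5 members above the free RNA limit the median was 1.62. Tnmd, a marker of mature tendon cells, was at 0.0804 and 8.75 CPM (109-fold, 36.9 to 531, from 3 UMIs at E11.5), Thbs4, a tendon matrix protein, was 30.0-fold higher (23.1 to 39.9), and Scx, the tendon progenitor transcription factor, was 2.51-fold higher (1.99 to 3.17). Mkx, a tendon transcription factor, had 6.30 and 5.48 CPM.

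Cartilage and bone genes of the mesenchyme split between early regulators and differentiation products. Of 15 measured chondrogenesis genes 10 were higher and 3 lower at E13.5, and the median log2 ratio was 1.96. Cytl1 and Acan, the latter the core protein of cartilage aggrecan, were 23.9-fold (14.7 to 41.4) and 18.9-fold (8.38 to 52.6) higher, at 10.9 and 3.03 CPM at E13.5. The 3 lower genes included Sox5, a cartilage transcription factor, 3.68-fold lower (2.79 to 4.91), and Col9a1, a chain of type IX collagen, 2.06-fold lower (1.91 to 2.22). Of 14 measured osteogenesis genes 9 were higher and 2 lower, with a median log2 ratio of 1.77. Smpd3 and Ifitm5, both active in mineralising bone, were 30.2-fold (18.1 to 54.5) and 25.8-fold (17.8 to 38.8) higher, while Runx2, the early osteoblast transcription factor, was at 21.4 and 14.2 CPM, 1.50-fold lower (1.34 to 1.69), and Spp1, which encodes osteopontin, was 5.45-fold lower (3.13 to 10.2). Ibsp, which encodes bone sialoprotein, was listed only in the E13.5 table, with 132 CPM in the mesenchyme. The cells named osteogenic progenitors by the authors, E13.5 cluster 5 with 422 cells, had no E11.5 cluster of the same name. An alternative left out this cluster and E11.5 cluster 10, which had Sox9 and Col9a1 among its 10 leading genes. The osteogenesis median was then 0.62 and the chondrogenesis median 0.23, while the matrix and tendon medians were 2.20 and 2.12. No cluster was left out for tendon or pericyte genes, so the tendon median still covers any such cells.

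Genes that pattern the distal mandible were lower at E13.5. Of 18 measured genes of this list 10 were lower and 2 higher, and the median log2 ratio was −1.05. Dlx5, a homeobox factor that specifies lower jaw identity, was at 158 CPM at E11.5 and 28.1 CPM at E13.5, 5.61-fold lower (5.24 to 6.01), and its relatives Dlx4 and Dlx2 were 6.79-fold (4.57 to 10.5) and 6.45-fold (5.68 to 7.35) lower. Msx1, a homeobox factor of distal and dental mesenchyme, was 2.65-fold lower (2.59 to 2.72), and Hand1 was 2.15-fold lower (1.98 to 2.32), both chosen after their values were seen. The 2 higher members included Hand2, 1.58-fold (1.51 to 1.66). Among 13 measured genes of oral and dental mesenchyme patterning 6 were higher and 2 lower, with a median log2 ratio of 0.45. Foxd1 and Osr1, transcription factors of the tongue and jaw mesenchyme, were 5.84-fold (5.06 to 6.76) and 4.01-fold (3.88 to 4.14) higher, and Pax9 and Barx1, transcription factors of tooth-forming mesenchyme, were 2.45-fold (2.21 to 2.72) and 2.11-fold (2.01 to 2.23) lower.

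The share of mesenchyme cells with a UMI of these regulators was compared after each cell was thinned to 2000 UMIs, which left out 0 E11.5 and 79 E13.5 mesenchyme cells. Dlx5 was detected in 24.1% of E11.5 cells (23.1 to 25.3%) and 4.03% of E13.5 cells (3.42 to 4.70%), or 51.6% and 11.1% without thinning. Msx1 was detected in 50.5% (49.2 to 51.8%) and 27.1% (25.7 to 28.5%), or 69.6% and 43.5% without thinning. Barx1 was detected in 18.8% (17.8 to 19.9%) and 8.05% (7.21 to 8.96%), or 37.1% and 20.4% without thinning. Osr2 was detected in 7.68% (7.01 to 8.39%) and 17.6% (16.4 to 18.9%), or 15.7% and 41.0% without thinning. Foxd1 was detected in 1.03% (0.792 to 1.33%) and 5.62% (4.91 to 6.4%), or 3.14% and 18.9% without thinning. In erythroid cells, which should lack these genes, the E11.5 shares were 2.19% for Dlx5, 14.5% for Msx1, 2.85% for Barx1, 0.658% for Osr2 and 0% for Foxd1, and none exceeded 0.485% at E13.5. Median depths were 5895 and 8303 UMIs in the mesenchyme and 13137 and 18517 UMIs in erythroid cells. Haemoglobin took 65.7% and 88.2% of the erythroid UMIs. Thinning such deep cells keeps a smaller part of any free RNA, so these background shares can be too low. The remaining fixed mesenchymal regulators (Lhx8, Sox9, Runx2, Sp7 and Scx) had shares of 21.8% and 19%, 5.31% and 4.16%, 3.81% and 2.06%, 1.58% and 2.38%, and 0.593% and 1.46%, against 2.85%, 0.439%, 0%, 0.219% and 0.439% in E11.5 erythroid cells, so Scx lay near background at E11.5. Without thinning the 5 shares were 44.9% and 45.5%, 12.9% and 12.4%, 11.6% and 7.45%, 4.76% and 6.99%, and 1.71% and 5.12%.

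A further question was whether GLI transcription factors, which carry Hedgehog signals, and HAND2, which patterns the distal jaw, are transcribed in the same cells. Gli2 (GRCm38, chromosome 1, 118834132 to 119053619) was at 11.2 and 14.2 CPM in the mesenchyme, a ratio of 1.26 (1.11 to 1.44). Gli3 (chromosome 13, 15463235 to 15730026) was at 26.9 and 26.4 CPM, a ratio of 0.981 (0.895 to 1.07). Hand2 (chromosome 8, 57320983 to 57324633) was at 78.6 and 124 CPM. After thinning, Hand2 was detected in 14.3% (13.4 to 15.2%) of E11.5 cells and 20.4% (19.1 to 21.7%) of E13.5 cells, Gli3 in 5.15% and 5.18%, Gli2 in 2.12% and 2.85%, and Hand1 in 8.05% and 3.87%, against 0.877% and 0% (Hand2), 0.658% and 0.485% (Gli3), 0% and 0% (Gli2) and 1.10% and 0% (Hand1) in erythroid cells. Unthinned, Hand2 was detected in 33.3% and 57.7% of cells, Gli3 in 15.2% and 19.3%, Gli2 in 6.80% and 11.5% and Hand1 in 13.8% and 8.83%. Both Gli3 and Hand2 were detected in 0.627% of E11.5 cells (37 of 5899, 0.442 to 0.864%) and 1.07% of E13.5 cells (41 of 3826, 0.770 to 1.45%). Independent detection of the 2 genes would give 0.738% and 1.06%, within both intervals. Without thinning, 5.78% (5.2 to 6.41%) and 12.2% (11.2 to 13.3%) of cells held both, and independent detection would give 5.05% and 11.1%, without allowance for deeper cells detecting more of every gene. Gli2 and Hand2 were detected together in 0.339% and 0.497% of thinned cells (0.304% and 0.582% if independent), and Gli2 and Gli3 in 0.170% and 0.131% (0.109% and 0.147%). Hand1 and Hand2 were detected together in 1.95% (1.61 to 2.34%) of E11.5 cells, above the 1.15% of independent detection, and in 1.15% (0.837 to 1.54%) of E13.5 cells, above 0.790%. Independent detection within each cluster would give 1.94% and 0.893%, which is close to the E11.5 share and lies inside the E13.5 interval, so an excess within clusters at E13.5 was not detectable at this depth.

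**Figure D2:**
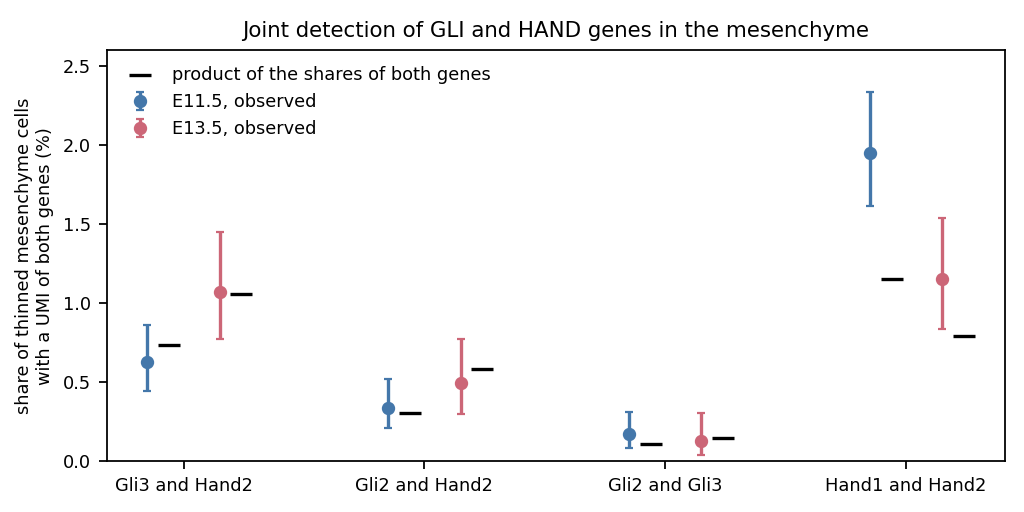
Points give the share of mesenchyme cells (y axis, %), each thinned to 2000 UMIs, with a UMI of both genes of a pair (x axis) at E11.5 and E13.5, with exact 95% binomial intervals, and black dashes give the product of the shares of both genes. Gli3 and Hand2 were found together in 0.627% and 1.07% of cells, close to the products of 0.738% and 1.06%.

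Signalling genes of the mesenchyme shifted in both directions. Of 11 measured hedgehog pathway genes 5 were higher at E13.5 and 0 lower (median log2 ratio 0.51). Hhip, a hedgehog-binding antagonist, was 8.75-fold higher (5.6 to 14.3) and Cdon, a co-receptor, 2.73-fold higher (2.39 to 3.13), while Sufu and Gli1 stood at 12.8 and 11.1 CPM and at 12 and 11.5 CPM. Of 18 WNT pathway genes 10 were higher and 5 lower (median 1.01). Sp5, a transcription factor and WNT target, was 25.6-fold higher (19.3 to 34.7) and Wnt11 8.15-fold higher (5.91 to 11.5), whereas Rspo2, a WNT agonist, and Lef1, a nuclear effector of WNT, were 3.60-fold (3.15 to 4.12) and 2.74-fold (2.59 to 2.89) lower. Of 14 FGF pathway genes 9 were higher and 2 lower (median 0.77). Fgf18 was 3.46-fold higher (2.72 to 4.42), Spry4, a feedback inhibitor, 3.37-fold higher (2.65 to 4.33), and Spry2 3.46-fold lower (3.00 to 4.00). Fgf8 was also lower, but at 1.85 CPM it lay within reach of free RNA from the epithelium. Of 14 BMP pathway genes 8 were higher and 1 lower (median 0.84). Chrdl1, a BMP antagonist, and Bmp5 were 8.80-fold (4.69 to 18.3) and 3.59-fold (2.80 to 4.64) higher, Bambi, a pseudoreceptor, was 1.93-fold lower (1.84 to 2.02), and Id2 was at 218 and 155 CPM.

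In the E13.5 mesenchyme the list medians of proliferation genes and early growth regulators were lower, and that of imprinted growth genes higher. Of 31 S phase genes 14 were lower and 0 higher (median log2 ratio −0.50), and of 39 G2M phase genes 16 were lower and 0 higher (median −0.47). Rrm2, a subunit of the enzyme that makes DNA precursors, was 3.49-fold lower (3.39 to 3.59) and Pcna, the replication clamp, 2.46-fold lower (2.34 to 2.58). Ect2 and Bub1, which act in cytokinesis and at the mitotic checkpoint, were 2.5-fold (2.25 to 2.79) and 2.04-fold (1.87 to 2.22) lower. Pola1 (20.7 and 21.8 CPM), Tubb4b (198 and 263 CPM) and Mki67 (101 and 124 CPM) were not lower. The authors' phase calls placed 68.3% of E11.5 mesenchyme cells in S or G2M (67.1 to 69.5%) and 43.0% of E13.5 cells (41.5 to 44.6%). These calls were not made at equal depth, and free RNA was not removed before them. Of cells thinned to 2000 UMIs, 41.1% and 25.4% held a UMI of Mki67 or Top2a. In erythroid cells these shares were 24.3% and 2.91%, but the authors placed 52.6% and 44.0% of erythroid cells in S or G2M. Dividing erythroid cells hold such transcripts themselves, so this class gives no background for cell cycle genes. Free RNA was therefore not measured here and stays open as part of the difference. Of 11 early embryonic growth regulators 8 were lower and 0 higher (median −1.76): Mycn, a growth-promoting transcription factor, was 6.06-fold lower (5.55 to 6.63), Sall4, a stem cell transcription factor, 9.19-fold lower (4.63 to 20.7), and Trim71, with 1 UMI at E13.5, had a ratio of 0.0253 (0.000626 to 0.149). Peg10 and Igf2bp2 were at 44.9 and 48.2 CPM and at 79.4 and 56.3 CPM. All 12 imprinted growth genes were at least 1.5-fold higher (10 of 12 with size factors, where Mest and Grb10 had log2 ratios of 0.48 and 0.47), from Mest (1.53-fold, 1.51 to 1.56) and Grb10 (1.53-fold, 1.49 to 1.57) to Meg3 (607 and 2647 CPM, 4.36-fold, 4.30 to 4.43) and Plagl1 (5.80-fold, 5.44 to 6.17).

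**Figure D3:**
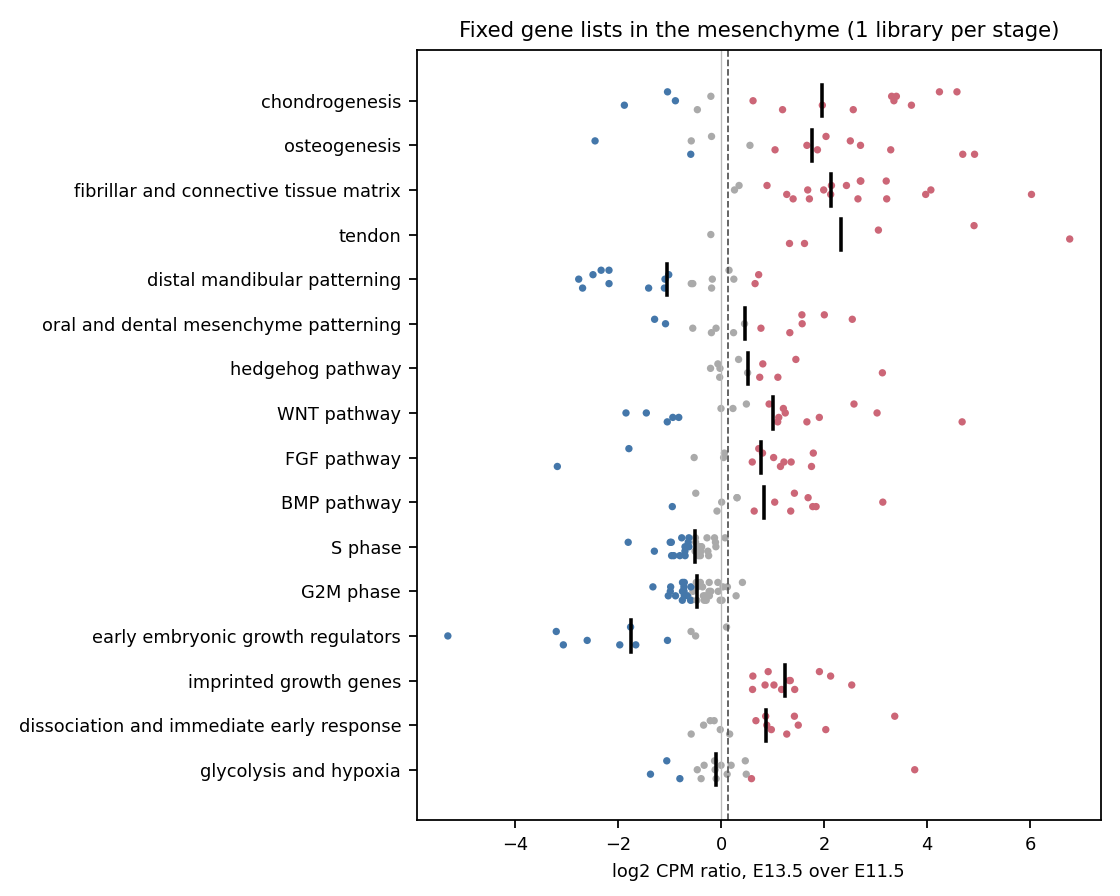
Each point is a measured gene of a fixed list (y axis) and its log2 CPM ratio E13.5 over E11.5 in the mesenchyme (x axis), red where at least 1.5-fold higher, blue where at least 1.5-fold lower and grey otherwise. Black bars are list medians, from −1.76 for early embryonic growth regulators to 2.34 for tendon, and the dashed line is the median of all genes, 0.14.

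Markers of handling also differed. Of 15 dissociation and immediate early genes, which respond to tissue dissociation, 9 were higher at E13.5 and 0 lower (median log2 ratio 0.86), led by Egr1 (0.214 and 2.22 CPM) and Ier3 (2.20 and 8.98 CPM), whereas Ier2 and Hspa8 were at 114 and 76.1 CPM and at 1850 and 1461 CPM. The median was −0.02 over the 9 members above the free RNA limit. Of 16 glycolysis and hypoxia genes 2 were higher and 3 lower (median −0.11). The only measured HOX gene of more posterior tissue, Hoxb2, was at 0.322 and 0.35 CPM. Against 10000 random lists of equal size and expression, the medians of matrix, chondrogenesis, osteogenesis, WNT and imprinted genes lay at the 100 percentile, tendon at 99.9, BMP at 99.6, dissociation at 99.2, FGF at 99.1, oral and dental patterning at 97.1, hedgehog at 96.0 and glycolysis at 24.2. Distal patterning, S phase, G2M phase and early regulators lay at percentile 0. The median log2 ratio of all genes in this class was 0.14, and relative to it the medians were 2.0 for matrix, 1.82 for chondrogenesis, 1.63 for osteogenesis, 2.19 for tendon, −1.19 for distal patterning, 0.31 for oral and dental patterning, 0.37 for hedgehog, 0.87 for WNT, 0.63 for FGF, 0.70 for BMP, −0.64 for S phase, −0.61 for G2M phase, −1.90 for early regulators, 1.11 for imprinted genes, 0.72 for dissociation and −0.25 for glycolysis. Different clusters held this class in the libraries, 0 to 8, 10 and 16 at E11.5 and 0, 2 to 6, 10 to 12, 14 and 21 at E13.5.

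Of all genes of the mesenchyme that met the naming rule, the 12 with the highest ratios included Agtr2, the type 2 angiotensin II receptor, at 1.34 CPM at E11.5 and 127 CPM at E13.5 (94.5-fold, 71.5 to 128), Stmn2, a microtubule-binding stathmin (25-fold, 21.6 to 29.1), and Egfl6, a matrix protein with EGF repeats (20-fold, 17.8 to 22.6). The matrix genes Eln and Dcn followed, the latter encoding decorin (15.7-fold, 14.5 to 16.9), with Nrp1, a receptor for semaphorins and VEGF (14.2-fold, 13.1 to 15.5), and Il11ra1, the interleukin 11 receptor (9.37-fold, 8.82 to 9.96). The transcription factors Mef2c and Ebf1 were 9.12-fold (8.42 to 9.90) and 8.47-fold (8.07 to 8.89) higher, and the RNA-binding protein gene Celf2, the opioid precursor gene Penk and Fibin were 8.50-fold, 8.06-fold and 7.26-fold higher. Among the 12 lowest, Mycn and Dlx5 were joined by Cited1, a transcriptional coregulator (4.18-fold lower, 3.98 to 4.40), Lix1 (4.14-fold, 3.89 to 4.40), Rrm2 and Kpna2, a nuclear import factor (4.30-fold, 4.08 to 4.54). The other 6 were Lrrc8a (11-fold lower, 9.79 to 12.3), Marf1 (6.89-fold), Dynlt1c (6.68-fold), Nme2 (4.96-fold), Fam60a (3.85-fold) and Dynlt1f (3.42-fold). These 6 and Rrm2 were lower beyond 2-fold in all 4 compared classes other than erythroid cells, as were 2 of the 12 genes with the highest ratios, in the other direction. Dynlt1c and Dynlt1f are near-identical members of 1 gene family, so their counts are uncertain. The annotation release is not given in the sources used here, so for genes lower in all 4 classes, Rrm2 among them, a difference in counting between libraries stays open. The same holds for Agtr2 and Il11ra1, which were higher in all 4 classes. The free RNA limit was not applied to the other classes in this count, and both genes were highest in the mesenchyme at E13.5. Free RNA therefore stays open for their ratios in the other classes. The muscle gene Myl4 was likewise higher in all 4 classes, with log2 ratios of 3.54 to 5.90.

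**Figure D4:**
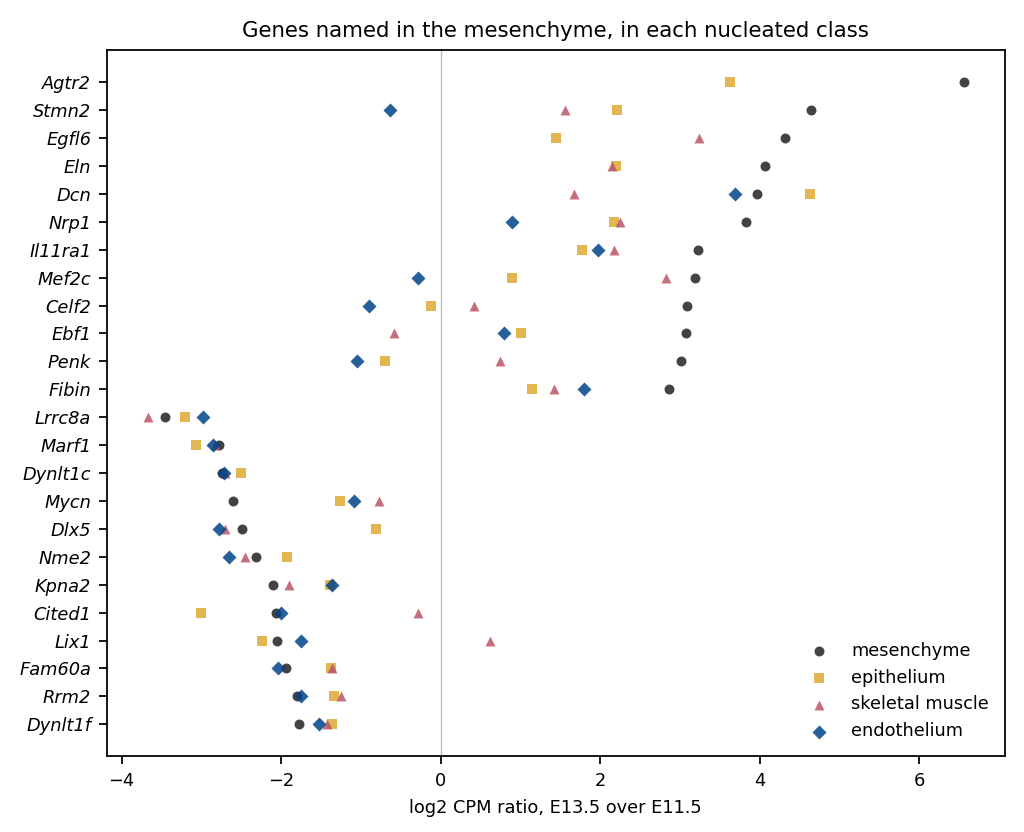
The log2 CPM ratio E13.5 over E11.5 (x axis) of the 24 genes named in the mesenchyme (y axis) in the mesenchyme, epithelium, skeletal muscle and endothelium, where measured with UMIs in both libraries. Lrrc8a lies between −3.67 and −2.98 in the 4 classes and Dynlt1c between −2.74 and −2.50, while Penk spans −1.04 to 3.01.

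The third comparison asked how the epithelium differed. Keratin and barrier genes were higher at E13.5: of 16 measured genes of epithelial stratification 10 were higher and 4 lower, with a median log2 ratio of 0.97 (percentile 100). Krt17, a keratin of periderm and stressed epithelium, was at 45.8 and 375 CPM (8.18-fold higher, 6.89 to 9.77) and Krt5, a basal keratin, at 132 and 712 CPM (5.38-fold, 4.86 to 5.97). Krt8, a keratin of simple epithelium, was 1.88-fold lower (1.64 to 2.15). The genes with the highest ratios were Krtdap, a protein of differentiating keratinocytes (1.01 and 121 CPM, 120-fold, 40.9 to 582), Dcn (24.8-fold, 19 to 33.2), Lgals7, an epithelial galectin (8.60-fold, 7.26 to 10.3), Krt17 and Lmo1, a transcriptional cofactor (6.27-fold, 5.52 to 7.14). E13.5 cluster 16, with 159 of the 838 epithelial cells, a median of 3061 UMIs and a median mitochondrial share of 13.8%, held Krtdap at 1263 CPM and Krt17 at 1483 CPM, against 8.16 and 78.0 CPM in cluster 7 and 17.9 and 497 CPM in cluster 9. Without it the stratification median was 0.28. Fgf8, a growth factor of the early oral epithelium, was at 155 CPM at E11.5 and 1.04 CPM at E13.5 (150-fold lower, 82.9 to 302), and Msx1 at 205 and 28.0 CPM (7.33-fold lower, 6.37 to 8.45). Marf1, Paip1 and Dynlt1c, the other genes with the lowest ratios, were 8.35-fold, 6.46-fold and 5.65-fold lower. Msx1, Marf1 and Dynlt1c were lower beyond 2-fold in all 4 compared non-erythroid classes, so a difference in counting stays open for them too. After thinning, Msx1 was detected in 25.2% and 4.04% of epithelial cells and in 14.5% and 0% of erythroid cells. Free RNA therefore stays open as part of the Msx1 difference.

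Dental and oral genes of the epithelium moved both ways, with 2 of 11 higher and 3 lower (median log2 ratio 0.22, percentile 98.1, and −0.16 over the 10 members with at least 100 UMIs). Wnt10a, a WNT ligand of tooth placodes, and Sostdc1, a BMP and WNT antagonist, were 2.69-fold (2.09 to 3.51) and 2.0-fold (1.86 to 2.16) higher, and Irx1, a homeobox transcription factor, was 2.08-fold lower (1.41 to 3.03). With thinning, which left out 46 E13.5 cells, Shh, the hedgehog ligand of tooth and tongue epithelium, was detected in 0.988% (0.270 to 2.51%) and 1.39% (0.695 to 2.47%) of epithelial cells, a difference not detectable at this depth, and in 4.20% and 4.42% without thinning (0% of erythroid cells). Median depths were 6507 and 12286.5 UMIs. FGF pathway genes had a median of 0.11 (3 of 11 higher, 4 lower, percentile 91.5), BMP genes 0.24 (1 of 11 higher, 3 lower, percentile 96.2), hedgehog genes 0.15 (1 of 11 higher, 0 lower, percentile 91.4) and WNT genes −0.11 (1 of 16 higher, 4 lower, percentile 46.8). Spry2, an FGF feedback inhibitor, was 8.51-fold lower (6.17 to 11.9), Etv4, an FGF target, 4.76-fold higher (2.78 to 8.84), and Bambi 3.14-fold lower (2.72 to 3.62).

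Early growth regulators were lower in the epithelium too, with 5 of 8 lower and 0 higher (median log2 ratio −0.70, percentile 0.160), among them Arid3b (6.37-fold, 3.73 to 11.1) and Mycn (2.39-fold, 2.10 to 2.72). S phase genes had a median of −0.32 (0 of 31 higher, 7 lower, percentile 2.93), G2M phase genes −0.13 (2 of 39 higher, 5 lower, percentile 66.7), imprinted growth genes −0.07 (1 of 12 higher, 2 lower, percentile 67.7) and glycolysis genes −0.19 (3 of 15 higher, 1 lower, percentile 29.2). The authors placed 51.9% (46.9 to 56.8%) and 54.1% (50.6 to 57.5%) of epithelial cells in S or G2M, and 26.9% (22.7 to 31.5%) and 28.5% (25.4 to 31.8%) of thinned cells held a UMI of Mki67 or Top2a. Dissociation genes had a median of 0.40 (6 of 14 higher, 1 lower, percentile 99.4), but −0.13 in cells thinned to 2000 UMIs. The median of all genes was −0.10, and the medians relative to it were 1.07 for stratification, 0.32 for dental and oral genes, −0.60 for early regulators and 0.50 for dissociation. Clusters 9 and 15 held this class at E11.5 and clusters 7, 9 and 16 at E13.5.

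The fourth comparison concerned skeletal muscle, from 151 and 752 cells. Genes of the contractile apparatus were higher at E13.5 in all 20 measured cases (median log2 ratio 4.04, percentile 100). The E13.5 class joined cluster 1 (509 cells, 3.54% in G1) with clusters 15 and 19 (163 and 80 cells, 84.0% and 100% in G1). Myl1 and Ttn were among the 10 leading genes of clusters 15 and 19, but not of cluster 1. No muscle cluster was left out, so a different mix of muscle cells stays open. Myl4, an embryonic myosin light chain, was at 17.5 and 1049 CPM (59.9-fold, 42.4 to 87.5), Actn2, an actinin of the Z disc, at 2.74 and 107 CPM (39.2-fold, 16.8 to 121), Ttn, which encodes titin, was 6.05-fold higher (5.11 to 7.23) and Tnnt1, a slow troponin, 2.29-fold higher (2.16 to 2.43). Myogenic regulators moved both ways, with 6 of 14 higher and 4 lower (median 0.28, percentile 99.6). Mef2c, which activates muscle genes, was 7.09-fold higher (5.67 to 8.99) and Met, the receptor of migrating muscle precursors, 3.05-fold higher (1.79 to 5.64), while Eya1, a regulator of early myogenesis, and Tcf21, a factor of branchiomeric muscle precursors, were 6.27-fold (4.35 to 8.98) and 3.69-fold (3.01 to 4.50) lower. Myod1 and Myog, which commit and differentiate myoblasts, were detected in 27.8% (20.8 to 35.7%) and 52.5% (48.9 to 56.2%), and in 25.2% (18.5 to 32.9%) and 46.8% (43.2 to 50.4%), of thinned cells, from which 0 and 4 cells were left out. Without thinning the shares were 68.2% and 89.1% for Myod1 and 45.0% and 67.6% for Myog, and in erythroid cells 0.219% and 0%, and 0.658% and 1.46%. Median depths were 11778 and 18848.5 UMIs.

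Mustn1, Cryab and Il17b, the first a small nuclear protein and the second a small heat shock protein of muscle, joined Myl4 and Actn2 as the muscle genes with the highest ratios, at 46.4-fold (19.8 to 143), 41.1-fold (25.3 to 72.0) and 39.3-fold (18 to 107). The lowest ratios were those of Pbld2 (134 and 1.77 CPM, 75.6-fold lower, 50.4 to 118), Dynlt1c, Nme2, Plk2, a cell cycle kinase (4.38-fold, 3.69 to 5.18), and Tpm3, a tropomyosin (3.83-fold, 3.41 to 4.29). All of these except Plk2 were lower beyond 2-fold in all 4 compared non-erythroid classes, so a difference in counting stays open for them too. Early growth regulators were lower in 8 of 9 cases (median −0.88, percentile 0.01), led by Lin28b, a blocker of let-7 processing (8.45-fold, 4.28 to 16.7), and Peg10 (2.70-fold, 2.19 to 3.30). Imprinted growth genes had a median of 0.56 (6 of 12 higher, 0 lower, percentile 100), with Meg3 6.20-fold (5.66 to 6.80) and Cdkn1c, an inhibitor of the cell cycle, 3.89-fold (3.73 to 4.06) higher. S phase genes had a median of −0.45 (0 of 31 higher, 7 lower, percentile 0.1), G2M phase genes −0.32 (0 of 39 higher, 4 lower, percentile 2.3), dissociation genes 0.29 (3 of 14 higher, 1 lower, percentile 94.4) and glycolysis genes −0.23 (1 of 15 higher, 4 lower, percentile 24.6). The authors placed 78.8% (71.4 to 85.0%) and 68.8% (65.3 to 72.1%) of these cells in S or G2M, and 44.4% (36.3 to 52.7%) and 37.3% (33.8 to 40.9%) of thinned cells held a UMI of Mki67 or Top2a, a difference not detectable at this depth. The median of all genes was −0.10, which puts the sarcomere median at 4.14 and the early regulators at −0.78 relative to it. Cluster 14 held this class at E11.5, named by its markers because the authors gave it no lineage, and clusters 1, 15 and 19 held it at E13.5.

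**Figure D5:**
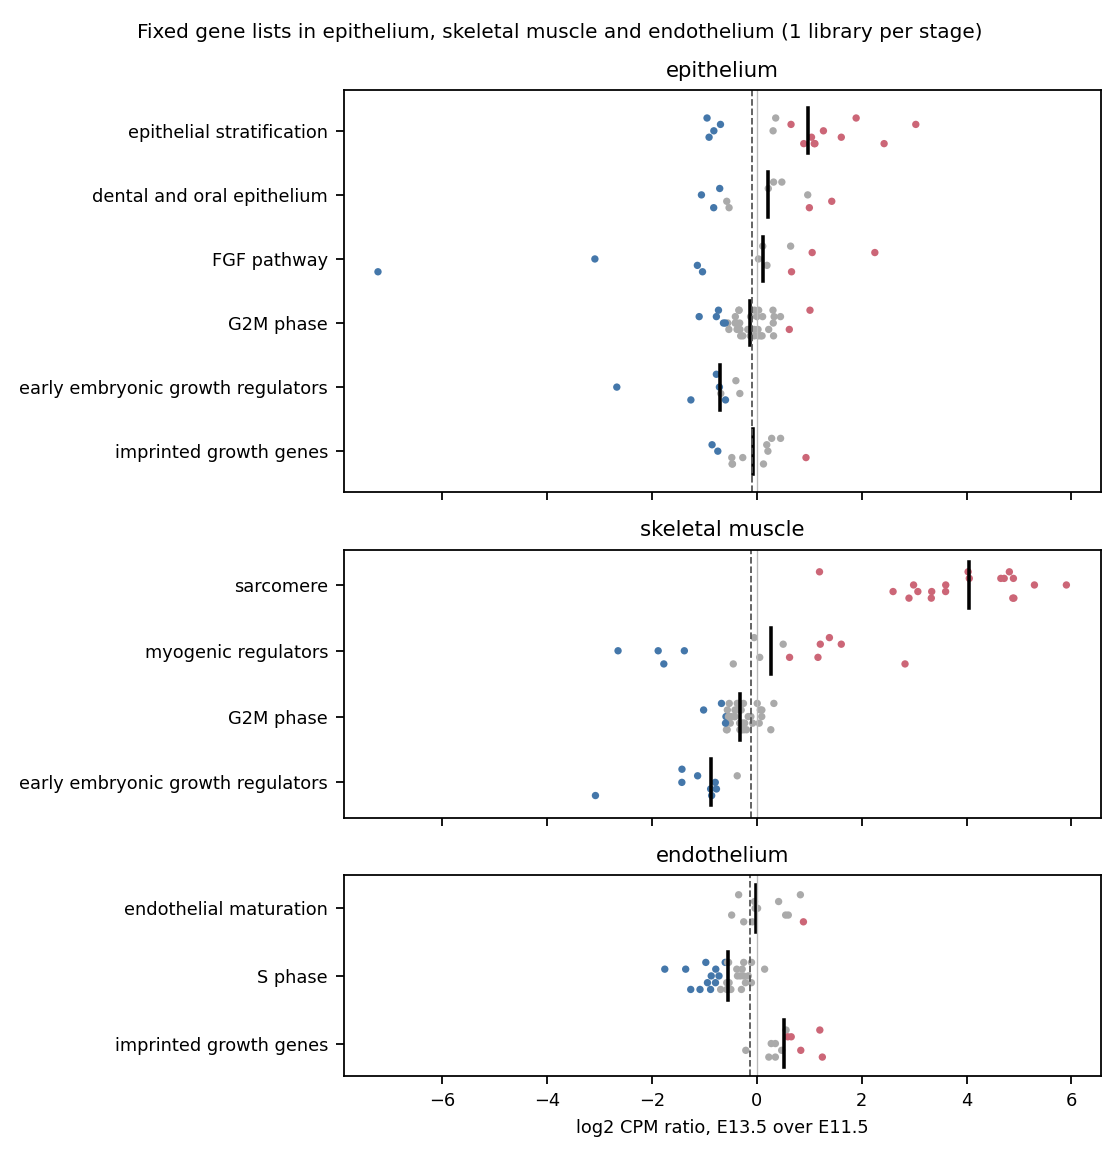
Each point is a measured gene of a fixed list (y axis) and its log2 CPM ratio E13.5 over E11.5 (x axis) in epithelium, skeletal muscle and endothelium, red where at least 1.5-fold higher, blue where at least 1.5-fold lower and grey otherwise, with list medians as black bars and the median of all genes as a dashed line. All 20 sarcomere genes lie above 0, with a median of 4.04, and endothelial maturation genes have a median of −0.01.

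The endothelium, from 162 and 137 cells, differed little in its maturation genes when counts were summed over cells. Of 12 genes 1 was higher and 0 lower (median log2 ratio −0.01, percentile 74.5). With the mean over cells of each cell's CPM this median was higher and past its interval, as given with the alternatives. Plvap, a component of fenestrated vessels, was 1.85-fold higher (1.64 to 2.09), and Nr2f2, a venous transcription factor, was at 63.5 and 45.5 CPM. Other genes were higher at E13.5, among them Igfbp7 (16.7-fold, 11.6 to 24.8), the caveola gene Sdpr (8.57-fold, 5.6 to 13.7), Gpihbp1, which anchors lipoprotein lipase to capillaries (6.76-fold, 4.78 to 9.82), and Clec14a (6.21-fold, 4.66 to 8.40). Ccl21a, a chemokine of lymphatic vessels, had 1 and 1779 UMIs, the latter in 7 of the 137 cells. The genes with the lowest ratios were the platelet genes Ppbp and Pf4 and the macrophage genes Tyrobp, C1qc and C1qb, at 253, 1540, 218, 123 and 155 CPM at E11.5 and 0.670, 20.8, 0.670, 0.670 and 1.34 CPM at E13.5. They mark other blood cells in the E11.5 cluster, where 22 of the 162 cells held at least 3 UMIs of macrophage markers and 9 held at least 3 of megakaryocyte markers, against 1 and 4 of 137 cells at E13.5. Without cells with a UMI of Pf4, Fcer1g, Tyrobp or Ptprc, the log2 ratio of C1qb was 0.72, and the medians were −0.15 for maturation, 0.32 for imprinted and −0.31 for glycolysis genes. S phase genes had a median of −0.56 (0 of 31 higher, 12 lower, percentile 0), G2M phase genes −0.22 (0 of 39 higher, 5 lower, percentile 23.6), early growth regulators −0.73 (0 of 7 higher, 5 lower, percentile 0.620), imprinted growth genes 0.52 (5 of 12 higher, 0 lower, percentile 99.96), glycolysis genes −0.52 (0 of 14 higher, 3 lower, percentile 0.690) and dissociation genes 0.05 (0 of 11 higher, 1 lower, percentile 83.9). The imprinted growth factor gene Igf2 was 2.38-fold higher (2.09 to 2.71) and Gnas, a G protein subunit, 2.3-fold (2.19 to 2.41). The median of all genes was −0.12. The early regulator median shrank with thinned cells, and the imprinted median in cells with no Xist UMI, as given with the alternatives.

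In erythroid cells, from 456 and 207 cells, haemoglobin genes took 65.7% of UMIs at E11.5 and 88.2% at E13.5, and the median log2 ratio of all genes was −2.52, so other genes are read relative to that value. Adult globins were higher in all 4 cases: Hbb-bt 8.50-fold (8.42 to 8.58), Hbb-bs 4.94-fold (4.92 to 4.97), Hba-a2 4.75-fold (4.64 to 4.87) and Hba-a1 1.88-fold (1.87 to 1.88), with a median of 2.28. Of the 3 embryonic globins, Hbb-bh1 was 6.14-fold lower (6.02 to 6.27), Hba-x 2.27-fold lower (2.25 to 2.28), and Hbb-y was at 365682 and 292786 CPM. With size factors over all genes, the log2 ratios of Hba-x and Hbb-y turned positive, 1.31 and 2.17. Hbb-bh1, with a log2 ratio of −2.62, lay close to the −2.52 of all genes. Read relative to that value, no embryonic globin was clearly lower. A larger haemoglobin share itself lowers the value of all other genes, so that value is no neutral scale for globins. Ratios between globins do not depend on the scaling. In erythroid cells Hbb-bs to Hbb-y was 0.107 at E11.5 and 0.662 at E13.5, and Hba-a1 to Hbb-y 0.415 and 0.974. Each embryonic globin was thus lower relative to the adult globins. The globin genes share near-identical sequence, so their split between copies is uncertain. Relative to all genes, S phase and G2M phase medians lay at −0.88 and −1.01 (percentile 0 for both) and early growth regulators at −0.19 (percentile 40.4). On the same scale dissociation genes lay at 1.75 (percentile 100) and glycolysis genes at 0.99 (percentile 99.4). In the order given, 17 of 31, 39 of 39, 0 of 7, 8 of 12 and 3 of 11 measured genes lay above the free RNA limit. Free RNA of other cells stays open for the rest. Hmox1, which degrades haem, was 30.0-fold higher (20.4 to 46.0), and Fam220a, Mkrn1, Nudt4 and Cd24a were 3.95-fold, 3.46-fold, 3.00-fold and 2.56-fold higher. Relative to the median of all genes these 5 genes were 172-fold, 22.6-fold, 19.8-fold, 17.2-fold and 14.6-fold higher. The lowest ratios were those of Acp5, Tmem14c, a haem synthesis transporter, Mrpl42, Slc39a8 and Rrm2, at 46.9-fold, 31.3-fold, 24.5-fold, 24.4-fold and 24.2-fold lower, or 8.21-fold, 5.48-fold, 4.29-fold, 4.27-fold and 4.24-fold lower relative to the median of all genes. Clusters 11 and 12 held this class at E11.5 and cluster 13 at E13.5.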

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

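The tests on Y-linked counts by library, on deep cells with Xist, on pseudogenes against coding genes, on pseudogenes of the epithelium and skeletal muscle, and on the spread of the globin ratio were chosen after the result was seen.

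Of the named or listed genes, 4 moved in opposite directions in 2 compared non-erythroid classes under a rule that asked, in each class, for at least 50 UMIs, an interval wholly beyond 1.5-fold, and at least 0.2 of the level in the highest class. Genes that missed 1 of these limits, such as Cryab (5.36 in skeletal muscle and −2.64 in epithelium) and Mest, are not counted. The 4 genes stand here for the gap between the log2 ratios of the classes, and the difference was not tested. Krt8, a keratin of simple epithelium, was higher at E13.5 in skeletal muscle (2.16) and lower in epithelium (−0.91), a gap of 3.07. Pax3, a regulator of muscle precursors and neural crest, was higher in mesenchyme (1.84) and lower in skeletal muscle (−1.77), a gap of 3.62. Pax9, a regulator of tooth mesenchyme, was higher in epithelium (1.20) and lower in mesenchyme (−1.29), a gap of 2.49. Sox6, a regulator of cartilage and of muscle fibre type, was higher in skeletal muscle (2.64) and lower in mesenchyme (−0.89), a gap of 3.53.

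Some counts stayed outside the comparisons because 1 of the tables does not list the gene. With over 1000 UMIs at E13.5 these were Ibsp (4638 UMIs, 4536 of them in the mesenchyme), BC023719 (1337), Cox6a2 (1127) and Myoz2 (1099). A gene missing from a table is not a measured 0. Cells outside the compared classes were those of E13.5 cluster 8 (304 cells), of E13.5 cluster 20 (73 cells), and the glia (26 cells at E11.5 and 102 at E13.5), which were too few or had no lineage name.

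Xist was at 0.0536 CPM in the E11.5 mesenchyme and 499 CPM at E13.5, where 1184 of 3905 mesenchyme cells (30.3%) held a UMI of it. E13.5 mesenchyme cells with Xist held 15.2% of the Y-linked CPM of cells without it (10.4 against 68.0 CPM), which a mix of XX and XY embryos could give. Xist raised in all cells is argued against by the 31.7% of deep E13.5 cells that held it. Xist counts lost at E11.5 would leave the Y-linked sums alike, and their ratio of E13.5 over E11.5 was 0.509 (0.480 to 0.539). That test needs equal Y-linked levels per XY cell in both libraries, which the values below do not show, so it cannot decide. A candidate explanation is that the E11.5 cells came almost wholly from male embryos and the E13.5 cells from both sexes. Lost Xist counts stay open. E13.5 cells without Xist held 68.0 CPM of Y-linked genes against 98.4 CPM in the E11.5 mesenchyme, and that part of the drop was not explained.

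Processed pseudogenes were lower than coding genes at E13.5 in the compared non-erythroid classes. The difference of median log2 ratios was −1.34 in the mesenchyme, and −0.63, −0.81 and −0.76 in the other 3 of these classes. Reads shared between near-identical copies and divided differently in the 2 libraries could give this. Over genes with at least 1000 UMIs the mesenchyme difference was −0.72, which argues against few counts as the whole cause there, while in epithelium and skeletal muscle it was −0.18 and 0.08, so few counts stay open in those classes, and in the endothelium it was 1.06 from only 2 pseudogenes. Regulation with stage was not tested and stays open.

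Haemoglobin transcripts made up 1.24% of UMIs in the E11.5 mesenchyme and 0.218% at E13.5. The ratio of Hba-a1 to Hbb-y spanned at most 1.29 times over mesenchyme, epithelium and skeletal muscle of a library, as a common pool of free RNA could give, yet it was 2.37 times lower in E11.5 mesenchyme than in captured erythroid cells. Doublets with erythroid cells are argued against as the main source in the E11.5 mesenchyme and in the epithelium. Their 5% of cells with the highest haemoglobin share held 5.45% (E11.5 mesenchyme), 4.89% (E11.5 epithelium) and 4.3% (E13.5 epithelium) of the haemoglobin UMIs. In the E13.5 mesenchyme the same 5% of cells held 12.7%, so a larger doublet part than at E11.5 stays open there. Doublets also stay open in skeletal muscle (31.9% and 38.4%) and endothelium (43.1% and 94.9%). A pool in proportion to the captured erythroid UMIs is argued against too: the haemoglobin share of the mesenchyme was 5.70 times higher at E11.5 and erythroid haemoglobin UMIs per cell 1.13 times, 5.05 times apart. Lysis of more primitive cells before capture stays open.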

How the results depend on the processing

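The alternatives with the E11.5 limits, without Xist, with markers without globins, without the highest doublet scores, with or without E11.5 cluster 17 or E13.5 clusters 16 or 21, without other blood cells and above the free RNA limit were chosen after the data were seen. No paired analysis was possible because each stage had 1 library. Where a value moved, the cause was not tested unless named.

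Without erythroid cells the mesenchyme share was 88.8% at E11.5 and 63.9% at E13.5, by construction of the smaller total. With cells of at least 2000 UMIs it was 64.9% at E13.5. With the E11.5 limits for both libraries the E13.5 shares were 65.8% (mesenchyme), 12.4% (epithelium), 12.9% (skeletal muscle) and 1.75% (endothelium). With the class set by the highest mean of all fixed markers, the shares at E11.5 and E13.5 were 0.324% and 36.7% for mesenchyme, 0.0986% and 12.0133% for epithelium and 0.0423% and 8.26% for skeletal muscle, since globin markers drew 7023 of 7099 cells at E11.5 and 2497 of 6318 at E13.5 into the erythroid class. With markers without globin genes they were 81.7% and 64.7% for mesenchyme and 14.7% for E13.5 epithelium, and the log2 ratio of C1qb in the endothelium turned to 0.80. In cells with no Xist UMI the E13.5 muscle share was 10.6%, the mesenchyme G2M phase median −0.52 and the sarcomere median 4.29.

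With size factors the mesenchyme medians were 1.63 for osteogenesis, 2.0004 for matrix, −1.19 for distal patterning and −0.61 for G2M phase, Peg10 turned to −0.036, and the stratification median was 1.07. In erythroid cells, where these factors remove the large shift of all genes, the medians turned to 1.72 for dissociation and 0.96 for glycolysis, and the log2 ratios to 1.31 for Hba-x, 2.17 for Hbb-y, 0.57 for Hells, 0.97 for Tubb4b, 1.63 for Ube2c, 0.93 for Peg10, 0.10 for Ier2 and 0.56 for Hspa8. With totals without haemoglobin, mitochondrial and ribosomal protein genes, the medians were 1.83 for osteogenesis, −0.99 for distal patterning, −0.41 for G2M phase, 1.09 for stratification and 0.72 for erythroid dissociation, and erythroid Hba-x, Hbb-y and Ube2c turned to 0.31, 1.16 and 0.63.

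With no minimum and 0.5 UMI added the osteogenesis median was 1.87. With at least 100 UMIs the epithelial medians turned to −0.16 for dental and oral genes and −0.066 for dissociation. With the mean over cells of each cell's CPM, distal patterning was at −1.15, G2M phase at −0.59, stratification at 1.18 and sarcomere at 3.63, and Junb in the endothelium turned to 0.45. With cells thinned to 2000 UMIs, the mesenchyme medians were 1.56 for osteogenesis, 2.06 for matrix, −1.15 for distal patterning, 0.78 for hedgehog and −0.58 for G2M phase, the sarcomere median was 3.19, epithelial dissociation turned to −0.13, Gli3 and Hells in the epithelium to 0.41 and −0.069, and Tubb4b and Hmga2 in the endothelium to −0.42 and 0.25. In cells with no UMI of Mki67 and Top2a, the medians were 1.62 for osteogenesis, 0.21 for hedgehog, −1.98 for G2M phase (a list that holds both genes) and 1.13 for stratification, Tubb4b turned to −0.39 in the mesenchyme and −0.68 in the endothelium, Grb10 in the endothelium to −0.025 and Ube2c in erythroid cells to 0.081.

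Without E11.5 cluster 10 and E13.5 cluster 5 the mesenchyme medians were 0.62 for osteogenesis, 0.23 for chondrogenesis, 1.37 for imprinted and −0.18 for glycolysis genes. Over members above the free RNA limit the osteogenesis median was 1.87, and the mesenchyme dissociation median turned to −0.017. Without E13.5 cluster 16 the stratification median was 0.28. Without cells with a UMI of Pf4, Fcer1g, Tyrobp or Ptprc, C1qb and Grb10 in the endothelium turned to 0.72 and −0.11, and the medians were −0.15 for maturation, 0.32 for imprinted and −0.31 for glycolysis genes. With a 2-fold rule 34 mesenchyme list members were lower, against 66. Cells with both Gli3 and Hand2 made up 5.78% and 12.2% with no thinning and 2.62% and 3.82% at 4000 UMIs. The share with a UMI of Mki67 or Top2a was 41.1% and 25.4%, a different measure from the phase calls.

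Other large moves were tendon at 1.62 with at least 100 UMIs or above the free RNA limit, oral and dental patterning at 0.09 with thinned cells, epithelial FGF genes at −0.38 in cells with no UMI of Mki67 and Top2a, muscle dissociation at −0.22 above the free RNA limit, and in the endothelium maturation at 0.49 with the mean over cells, early regulators at −0.14 with thinned cells and imprinted genes at 0.14 in cells with no Xist UMI. Over all alternatives, these values included, 142 of 667 list medians moved past their interval and a further 7 were counted as turned in direction. The epithelial FGF, muscle dissociation and endothelial maturation medians above also changed sign, but are among the 142 and not the 7. A list median was counted as turned only where it stood out from the random lists in the main analysis, whatever its interval. These medians did not (percentiles 91.5, 94.4 and 74.5). Their main intervals held values of both signs (−0.21 to 0.45, −0.14 to 0.72 and −0.10 to 0.26). The embryonic globin median did not stand out either (percentile 84.9), and its interval was −1.19 to −1.17. Its middle gene, Hba-x, turned to 1.31 and 0.31 with the other scalings above. That median turned with it and is not among the 7. For values of single genes the same counts were 442 and 24 of 2813. Of the rest, 76 of 448 counts of members, 30 of 96 shares of cells, 60 of 90 regulator shares, 11 of 30 cell cycle shares and 4 of 10 shares with 2 genes moved. The planned automatic doublet calls gave too few cells to be of use, the class by all fixed markers left too few cells for lists in 4 compared non-erythroid classes, and muscle cells with no UMI of Mki67 and Top2a numbered 23 at E11.5, so these gave no list values.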

Other observations

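Glia were present at both stages, with 26 and 102 cells. Sox10, the transcription factor of neural crest-derived glia, was at 408 and 305 CPM, a ratio of 0.748 (0.602 to 0.936), and Fabp7, a lipid-binding protein of immature glia, was at 377 and 686 CPM (1.82-fold higher, 1.47 to 2.27). Stmn2 was found in 15 E13.5 cells of this class (364 UMIs).

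The E13.5 cluster that the authors named mast cells led with macrophage genes: Csf1r, the macrophage growth factor receptor, was at 367 CPM in 54 of its 73 cells, C1qa, a complement gene, at 945 CPM in 49, and Mrc1, a mannose receptor, at 568 CPM in 48. The mast cell protease genes Cpa3 and Cma1 were at 505 and 414 CPM, in 11 and 10 cells. Among the epithelial clusters, E11.5 cluster 9 held Fgf8 at 225 CPM, against 2.16 CPM in cluster 15, and cluster 15 held Cxcl14, a chemokine gene, at 2886 CPM and Tfap2b, an ectodermal transcription factor gene, at 430 CPM, against 360 and 27.9 CPM. At E13.5 clusters 7 and 9 held Cxcl14 at 3415 and 70.1 CPM and Lmo1 at 998 and 54.5 CPM. In the E13.5 endothelium, 1 cell held 631 of the 1779 UMIs of Ccl21a.

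E13.5 cluster 8, which the authors gave no lineage, held 255 of 304 cells under 2000 UMIs, and haemoglobin made up 24.1% of its UMIs. In the E13.5 endothelium haemoglobin made up 3.4% of UMIs, of which the 5% of cells with the highest share held 94.9%. Xist at E11.5 was found as 17 UMIs in 16 of 7099 cells.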
